A study of Homo sapiens with 5 samples.

How the data were processed

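DNA methylation was measured by whole-genome bisulfite sequencing in 5 human prostate cell lines, with 1 library per line. Per the labels' protocols, genomic DNA was fragmented by sonication, ligated to methylated adapters, converted with bisulfite, amplified by PCR and sequenced in pools. The cancer group held Du145, LNCaP clone FGC and PC-3 (3 lines), and the normal group held PWR-1E and RWPE-1 (2 lines). The lines were the replicates of a group, so the p-values of regions and of single values rest on the spread between these lines. Those of the gene lists instead set the promoters of a list against other promoters, under a preset or estimated correlation. A small p-value of a list therefore does not stand for replication over lines.

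The deposited tables give, per the file headers, the coverage of each CpG site as a count of reads and the share of those reads that were methylated or unmethylated as a percent. The strand column holds a single value throughout, and whether the strands of a CpG were merged was not given in the sources used here. The submitters' processing notes name Trim Galore 0.6.7, cutadapt 4.1, Bismark, Bowtie2 2.1.0, methylKit and the genome build hg38. The role of each tool, any removal of duplicate reads and any coverage filter were not given in the sources used here. Sites with 1 read were present in the tables. The methylated reads of a site were taken as the coverage times the percent, and for coverage up to 100 reads this gave whole numbers within 0.06 reads at 100% of the sites of every library. PCR reads without molecular identifiers are not independent molecules, so the intervals given here cover counting error only.

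Chromosomes 1 to 22 and X were used. They held 26191390 CpG sites with 262553116 site reads in Du145, 27997331 sites with 389487082 in LNCaP, 18085935 sites with 396191866 in PC-3, 18552499 sites with 350472951 in PWR-1E and 26645192 sites with 268775515 in RWPE-1. A site entered with a coverage of at least 5 reads and at most the 99.9th percentile of the library, which was 53, 77, 505, 333 and 45 reads in the same order. In Du145 74.95% of the sites had 5 or more reads, against 89.6% in LNCaP, 65.1% in PC-3, 64.0% in PWR-1E and 77.6% in RWPE-1. On the autosomes 8465089 sites passed in all 5 libraries.

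The libraries fell into a technical split that crosses the groups. Coverage varied between sites with a coefficient of variation of 1.76 in PC-3 and 1.52 in PWR-1E, against 0.704 in Du145, 0.607 in LNCaP and 0.660 in RWPE-1. In PC-3 and PWR-1E coverage rose with local CpG density. Values within the split were therefore computed as PC-3 minus PWR-1E and as the mean of Du145 and LNCaP minus RWPE-1.

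Gene positions and symbols came from a table of the assembly GRCh38.p14, which has the coordinates of hg38 and gives no strand and no sequence. The 153 protein-coding entries on other scaffolds were left out. The 5′ end of each of 19821 protein-coding genes was inferred from the sites themselves, as the end with at least 20 CpG sites around it and at least 2 times as many as the other end. This settled 13301 genes (67.1%). Among 495 settled genes with a divergent transcript starting beside 1 end, the inferred end was the one beside it for 491 (99.2%). Settled genes without such a transcript were not checked. The share may be lower among them, above all where the inferred end has few CpG sites, and single genes may have the wrong end. The rule selects genes whose 5′ end is rich in CpG, and the other 6520 genes entered no test. CpG islands were planned with a genome sequence and were not tested. In their place, chosen after seeing the data, CpG-dense regions were formed by merging windows of 500 bp with at least 25 sites, which gave 55996 regions with a median length of 859 bp. Repeat-masked sequence was not analysed here.

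A promoter ran from 1000 bp upstream to 500 bp downstream of the inferred end and was tested with at least 3 passing sites in every library, a CpG-dense region with at least 5, a 100-kb window with at least 50 and a 10-kb window with at least 20. The level of a region was methylated reads over all reads of its sites. Genome-wide levels and levels by annotation were unweighted means over autosomal sites, and a 10-kb window was called partially methylated when its mean site level was under 60%.

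Regions were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test on methylated and unmethylated read counts, with 1 intercept per library, the group as the effect, and Benjamini-Hochberg adjustment over all regions of a kind. A call needed an adjusted p under 0.05 and a difference of at least 20 percentage points between the group means. Single values such as the genome-wide level were compared by a two-sided exact permutation test over the 10 splits of the 5 libraries into 3 and 2, whose smallest possible p is 0.1. Beside the calls, and added after seeing the data, regions were counted as separated when all 3 cancer lines lay on the same side of both normal lines, which a random order of the 5 lines gives for 20% of regions. The 20 gene lists were tested by camera in limma 3.58.1 on the log2 odds of methylation with an offset of 0.5, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other promoters, so a list can lie below the others while its own difference is above 0. Levels, intervals and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and intervals of single levels are exact Clopper-Pearson 95% intervals.

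The tests were tested on simulated data for the comparison of 3 cancer with 2 normal lines over 13065 promoters, of which 100 were changed by 4 and 100 by 8 on the log2 odds scale. The quasi-likelihood test called 0 of them at either size, although 75% and 96% had an unadjusted p under 0.05. Limma called 0 of the 100 at a change of 4 and 45 of the 100 at a change of 8. The likelihood ratio test of edgeR called 36 and 93 of the 100, and also 56 of 12865 unchanged promoters.

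The groups, tests, gene lists and the first set of alternatives were fixed before the data were examined. The rule for naming took the 10 largest differences each way among called promoters and 3 windows each way among called windows, which gave none because nothing was called. It further took up to 4 called or otherwise 2 members with the largest absolute difference from each list, list members at least 60 points from each of the other 4 lines, and 6 genes in any case, among them GSTP1, KLK3, CDH1, TP63 and CDKN2A. A few of the results that this rule selects are not reported here. Promoters and regions named outside this rule, chosen after their values were seen, are the 10 separated promoters with the largest difference each way, the promoters past the threshold within their list, the promoters called with a shorter promoter, the 3 regions or windows with the largest difference each way, and 3 genes whose 5′ end was not settled. The homeobox gene list and the other lists hold few shared genes: GSTM2, GPX3 and GSTP1 stand in 2 lists, as do HOXD3, APC, DKK3, ZNF154 and SOX17.

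Settings chosen before the data were examined were a coverage minimum of 10 reads, every deposited site, no upper coverage limit, limma or the likelihood ratio test, no minimum or a 40-point difference, autosomes alone, reads thinned to the shallowest library, other promoter lengths, at least 10 sites per promoter, 50-kb windows, other limits for partial methylation, an estimated correlation, and leaving out each line in turn. Added after seeing the data were the sites passing in all 5 libraries (planned for the genome-wide level alone), leaving out lines for 100-kb windows by gene content, unweighted site means there, coverage evenness as a term, a stricter density of 35 sites, levels standardised by CpG density, means over 10-kb windows and list tests centred on ribosomal protein promoters.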

Results

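Whole-genome bisulfite sequencing, in which unmethylated cytosines are read as T and methylated ones as C, was carried out on 5 human prostate cell lines with 1 library each. The cancer lines were Du145, LNCaP clone FGC and PC-3 (n = 3), grown from metastases of prostate carcinoma in the brain, a lymph node and bone. The normal lines were PWR-1E and RWPE-1 (n = 2), prostate epithelial cells immortalised with viral genes. Mean coverage per CpG site was 10.02 reads in Du145, 13.9 in LNCaP, 21.9 in PC-3, 18.9 in PWR-1E and 10.1 in RWPE-1. Coverage was uneven in PC-3 and PWR-1E, which reached 2.61 and 2.78 times their own mean at the densest CpG sites, and even in the other 3 lines (0.895, 0.757 and 0.946 times in Du145, LNCaP and RWPE-1). Levels are percentages of methylated reads, coordinates are hg38, and values of single lines have no replicate.

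**Figure D1:**
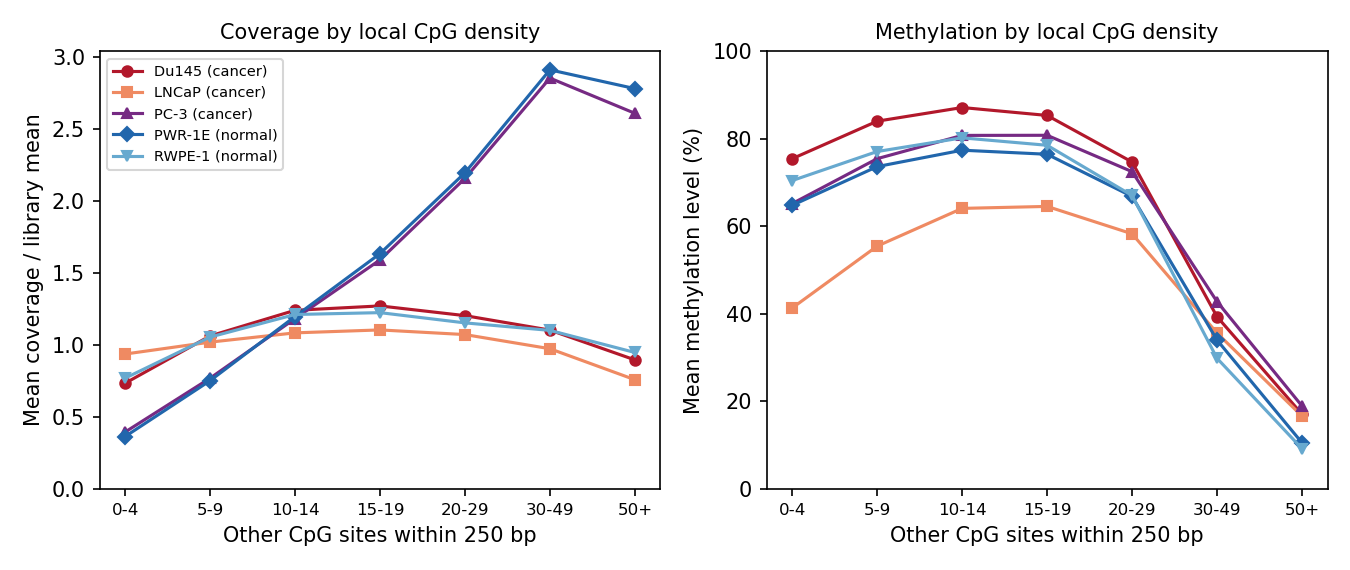
The left panel plots mean coverage divided by the library mean, and the right panel mean methylation level in percent, against the number of other CpG sites within 250 bp, with 1 line per library. Coverage of PC-3 and PWR-1E climbs from 0.393 and 0.362 times the mean at the sparsest sites to 2.61 and 2.78 times at the densest, and LNCaP lies lowest in methylation at the sparsest sites, at 41.3%.

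The first comparison asks which promoters differ in methylation between the 3 cancer lines and the 2 normal lines. Promoters carried more methylation in the cancer lines: the mean promoter level was 21.6% ± 1.33 (SD, n = 3) in the cancer lines and 15.5% ± 1.72 (SD, n = 2) in the normal lines. Promoters of basal epithelial genes, of transcription factors that pattern the embryo, of homeobox cluster genes, of neuroendocrine genes and of genes known for hypermethylation in prostate cancer stood out by camera with its preset correlation. With an estimated correlation 0 of the 20 lists passed, at a smallest adjusted p of 0.209 (camera with Benjamini-Hochberg adjustment). KRT5, a keratin of basal epithelial cells, was at 80.1% ± 19.5 (SD, n = 3) in the cancer lines and 0.200% ± 0.282 (SD, n = 2) in the normal lines. PTGS2, which encodes the inducible cyclooxygenase, was at 62.2% ± 4.94 (SD, n = 3) against 0.765% ± 0.455 (SD, n = 2).

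The tests and counts behind this were as follows. Of 13065 promoters, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 higher and 0 lower, with a smallest adjusted p of 0.323, while 797 had an unadjusted p under 0.05, 780 of them higher and 17 lower in cancer. Limma called 0, with 933 promoters at an unadjusted p under 0.05, and the likelihood ratio test of edgeR called 91 higher and 1 lower. Group means differed by at least 20 points in 1424 promoters higher in cancer and 106 lower. In 881 higher and 37 lower of these, all 3 cancer lines lay on the same side of both normal lines. Without a minimum difference 22.3% of promoters were separated in this way, against 20% by chance order, in 2722 promoters upward and 192 downward. With a line left out the order is met more easily, by 33.3% of random orders without a cancer line and 50% without a normal line, so counts of separated regions with a line left out are not comparable with those over all lines. For promoters they were 1327 higher and 57 lower without LNCaP and 1361 and 121 without RWPE-1. The lower count was 143, 70 and 95 without Du145, PC-3 or PWR-1E. Within the unevenly covered pair, PC-3 lay at least 20 points above PWR-1E at 1508 promoters and below it at 195. Within the evenly covered lines, Du145 lay above RWPE-1 at 1628 promoters and below it at 181, and LNCaP above at 1502 and below at 536.

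Basal epithelial genes build the keratin network, desmosomes and basement membrane contacts of the basal layer. Of the 24 genes listed 13 had a measured promoter. The median difference of these 13 promoters was 23.2 points, which became 14.1 at the sites passing in all 5 libraries, 9.93 with unweighted means there, 14.4 without RWPE-1 and 32.4 without PWR-1E. Of the promoters 7 were at least 20 points higher in the cancer lines and 0 lower. Adjusted over the list alone, edgeR's quasi-likelihood test called 4 higher with Benjamini-Hochberg adjustment: KRT5 (adjusted p = 0.00326), TRIM29 and DSC3 (both 0.0119) and KRT6A (0.0459). The KRT5 promoter (chromosome 12, 52519894 to 52521394, 38 sites, 472 to 1168 reads per line) was at 91.6% in Du145, 57.6% in LNCaP and 91.2% in PC-3. It was at 0% in PWR-1E, where 472 reads allow up to 0.778% (exact 95% interval), and at 0.399% in RWPE-1. KRT6A, another keratin, was at 73.7% ± 25.6 (SD, n = 3) against 4.49% ± 5.17 (SD, n = 2). TRIM29 was at 78.1%, 70.2% and 70.4% in Du145, LNCaP and PC-3 and at 0.922% and 10.1% in PWR-1E and RWPE-1. DSC3, a desmosomal cadherin, was at 53.8%, 74.6% and 15.9% against 0.580% and 2.91%. TP63, the transcription factor of basal cells, did not follow them at the promoter inferred here: it was at 93.7% ± 6.64 (SD, n = 3) in the cancer lines and 97.2% ± 0.115 (SD, n = 2) in the normal lines, adjusted p = 0.976 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That promoter lies at the outer end of the gene (chromosome 3, 189595746 to 189597246). Starts inside TP63 were not examined as promoters, so whether they follow KRT5 stays open.

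**Figure D2:**
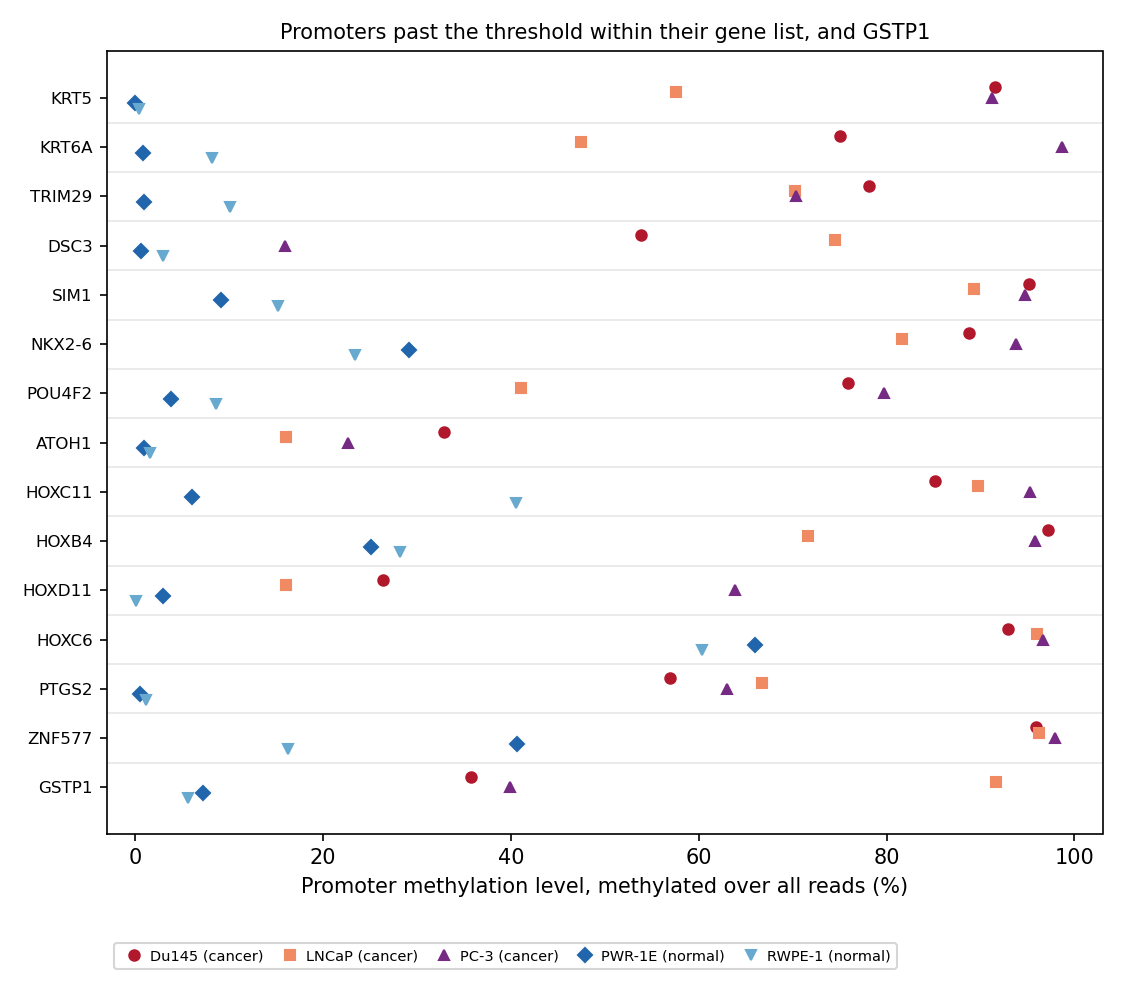
Methylation level in percent (x axis) of 15 promoters (y axis) in each of the 5 lines, with 1 point per library and no error bar. In 14 promoters past the threshold when adjusted over their gene list alone, and in GSTP1, every cancer line lies to the right of both normal lines, with KRT5 at 57.6% to 91.6% against 0% and 0.399%.

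Developmental transcription factors set cell identity in the embryo and are mostly silent in adult epithelium. The median promoter of the 78 measured was at 41.1%, 32.8% and 53.8% in Du145, LNCaP and PC-3 and at 10.2% and 15.9% in PWR-1E and RWPE-1. The median difference was 27.2 points, with 49 promoters at least 20 points higher in cancer and 1 lower. Adjusted over the list alone, edgeR's quasi-likelihood test called 5 higher with Benjamini-Hochberg adjustment, among them SIM1 (adjusted p = 0.00559), NKX2-6 and POU4F2 (both 0.0284) and ATOH1 (0.0370). SIM1, a factor of hypothalamic neurons, was at 93.1% ± 3.24 (SD, n = 3) against 12.2% ± 4.30 (SD, n = 2), over 758 to 3581 reads per line. ATOH1, which directs sensory and secretory cell fates, was at 32.9%, 16.1% and 22.7% in the cancer lines and at 0.963% and 1.57% in PWR-1E and RWPE-1.

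Homeobox cluster genes give position along the body axis. The median difference of the 27 measured was 22.6 points, with 14 at least 20 points higher in cancer and 0 lower. Adjusted over the list alone, HOXD11, HOXC11, HOXC6 and HOXB4 were called higher by edgeR's quasi-likelihood test, all at a Benjamini-Hochberg adjusted p of 0.0484. HOXC11 was at 90.1% ± 5.11 (SD, n = 3) against 23.3% ± 24.4 (SD, n = 2), and HOXB4 at 88.2% ± 14.3 (SD, n = 3) against 26.6% ± 2.15 (SD, n = 2). HOXC6 was already at 65.9% in PWR-1E and 60.4% in RWPE-1 and at 92.9% to 96.7% in the cancer lines.

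Neuroendocrine genes encode granule proteins and neuronal factors of hormone-secreting cells. The median difference of the 19 measured was 29.4 points, with 13 at least 20 points higher in cancer, 0 lower and 0 called over the list alone (smallest adjusted p 0.0676, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ELAVL4, a neuronal RNA-binding protein, was at 74.1% ± 29.6 (SD, n = 3) against 19.9% ± 18.8 (SD, n = 2). UCHL1, a neuronal ubiquitin hydrolase, was at 85.9% in LNCaP and 85.03% in PC-3, but at 10.1% in Du145, below PWR-1E (18.4%) and RWPE-1 (22.5%).

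The list of genes known for hypermethylation in prostate cancer had 31 measured promoters and a median difference of 21.4 points, with 17 at least 20 points higher and 0 lower. PTGS2 alone passed when adjusted over the list (chromosome 1, 186679923 to 186681423, adjusted p = 0.00302, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). GSTP1, a glutathione transferase and the best known methylation marker of prostate cancer, was at 35.8% in Du145, 91.7% in LNCaP and 39.9% in PC-3, and at 7.16% in PWR-1E and 5.63% in RWPE-1. Its promoter (chromosome 11, 67582812 to 67584312, 106 sites) was read 675 to 2433 times per line and gave an adjusted p of 0.752 over all promoters by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TAMALIN, listed under its older symbol GRASP, was at 25.2% in Du145, 88.9% in LNCaP and 90.1% in PC-3 against 17.3% and 15.8%. Of the glutathione and antioxidant genes, which share GSTP1, GSTM2 and GPX3 with this list, 29 were measured with a median difference of 0.305 points. GPX3, a secreted peroxidase, was at 91.7% in LNCaP and 98.1% in PC-3 but at 8.12% in Du145, with 3.58% in PWR-1E and 42.0% in RWPE-1.

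Across the 20 lists, camera with its preset correlation and Benjamini-Hochberg adjustment placed 5 above the other promoters: developmental transcription factors (adjusted p = 1.68e-09), neuroendocrine genes (6.41e-06), prostate cancer hypermethylated genes (1.82e-05), basal epithelial genes (9.72e-05) and homeobox cluster genes (0.00099). It placed 3 below them: olfactory receptor genes (8.6e-05), cancer-testis and germline genes (0.0317) and antigen presentation and interferon genes (0.0453). With an estimated correlation the adjusted p of these 8 lists by camera lay between 0.209 and 0.622. The olfactory call rested on LNCaP (camera adjusted p = 0.628 without it). The cancer-testis call was lost without LNCaP (camera adjusted p = 0.883) and without PWR-1E (0.308), and at the sites passing in all 5 libraries (0.239), and the antigen presentation call without any 1 of the 5 lines (camera adjusted p from 0.0691 to 0.255).

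Olfactory receptor genes, which are expressed in nasal neurons, had a median difference of -6.71 points over 25 promoters, out of 387 genes in the list. The other members had no settled 5′ end or too few passing sites. The list result therefore holds for the few members with a CpG-rich end and not for the family. The median level of the 25 was 26.9% in LNCaP, 80.8% in Du145, 64.4% in PC-3, 45.1% in PWR-1E and 68.0% in RWPE-1. OR10G6 was at 1.31% in LNCaP and 3.36% in PC-3 against 76.9% in Du145, 74.6% in PWR-1E and 88.2% in RWPE-1, whereas OR3A2 was at 68.8% ± 29.8 (SD, n = 3) in the cancer lines and 25.2% ± 17.3 (SD, n = 2) in the normal lines. Cancer-testis and germline genes, normally expressed in germ cells, had a median difference of -1.33 points over 29 promoters, while their median difference on the log2 odds scale was 0.17. MAGEA4 was at 24.7% in LNCaP and at 84.1% to 100% in the other 4 lines, and TDRD5 at 57.0% ± 25.6 (SD, n = 3) against 21.5% ± 3.65 (SD, n = 2). Of 38 antigen presentation and interferon genes 11 were measured, with a median difference of 0.829 points and a mean difference of -0.07. The sign of that median is opposite to the direction of the test. IFIT1, an interferon-induced antiviral gene, was at 52.0% in LNCaP and at 94.9% to 95.8% in the other lines. Its end (chromosome 10, 89405987 to 89407487, 33 sites) was inferred from CpG sites alone, so this region may not be the IFIT1 promoter. CGAS, the sensor of cytosolic DNA, was at 70.3% in LNCaP and 26.1% to 40.03% elsewhere.

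**Figure D3:**
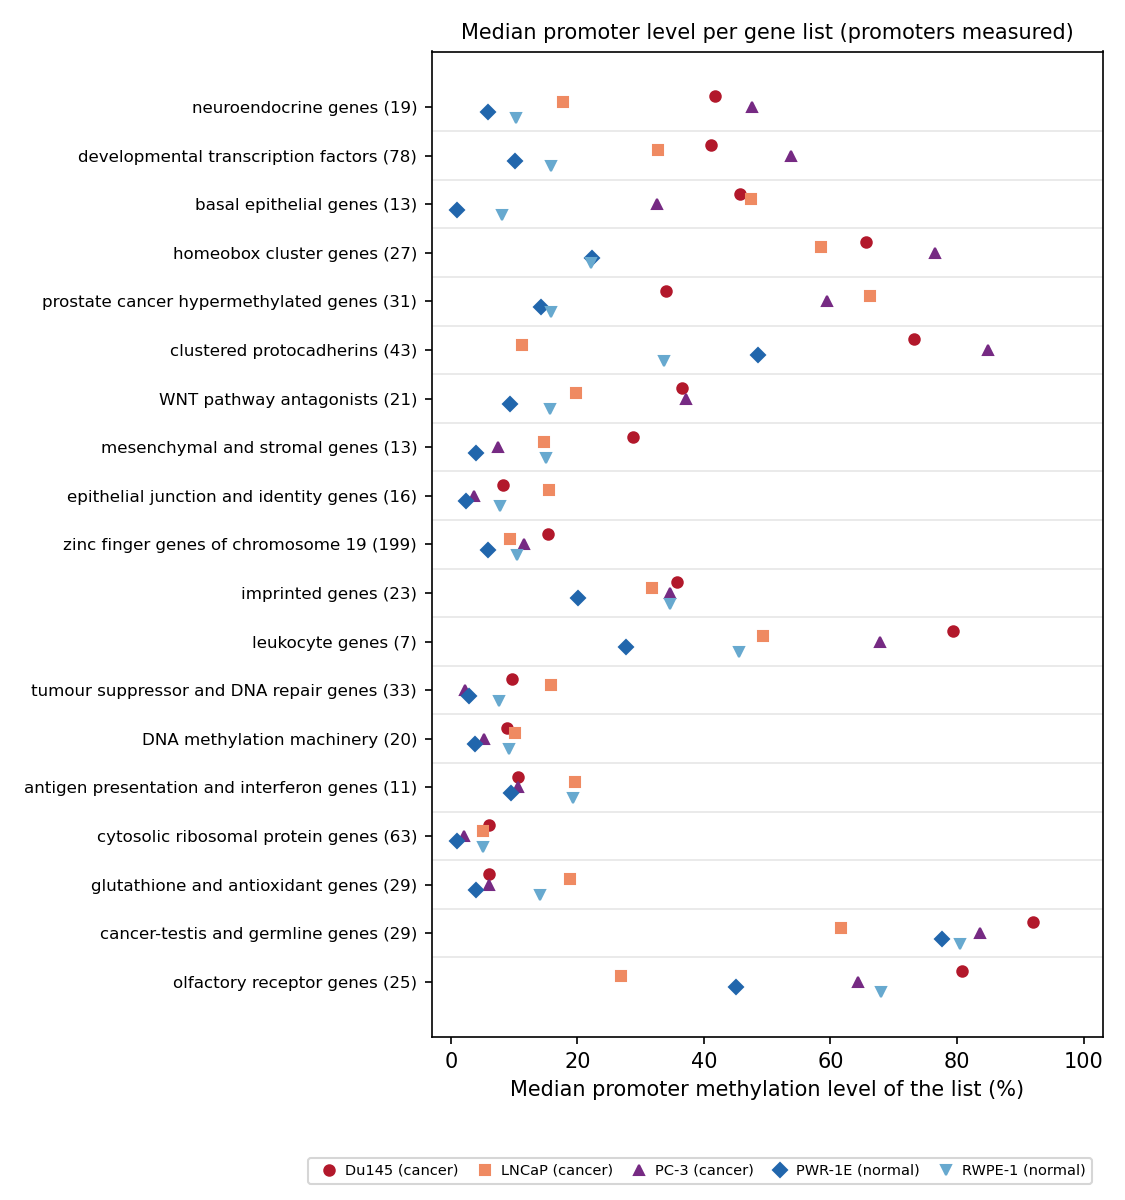
Median promoter methylation level in percent (x axis) of 19 gene lists (y axis, with the number of promoters measured) in the 5 lines, 1 point per library without error bars. The median of the 78 developmental transcription factors lies at 32.8% to 53.8% in the cancer lines and at 10.2% and 15.9% in the normal lines, and that of the olfactory receptor genes at 26.9% in LNCaP.

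The other 12 lists did not pass camera's threshold with the preset correlation. Clustered protocadherins, neuronal adhesion genes in a tandem array, had a median of 73.2% in Du145 and 84.96% in PC-3 but 11.3% in LNCaP, against 48.6% in PWR-1E and 33.8% in RWPE-1 (camera adjusted p = 0.0768, downward). Their camera direction depended on the lines: without LNCaP the list lay above other promoters (adjusted p = 3.78e-05), and it lay below them without Du145 (0.00607), PC-3 (7.58e-06) or RWPE-1 (0.000384). These calls use the preset correlation of 0.01, while the correlation estimated within the list was 0.481, and with estimated correlations camera's adjusted p over all lines was 0.766. PCDHA5 was at 38.4%, 4.62% and 4.93% in Du145, LNCaP and PC-3 against 63.7% and 53.7%, and PCDHGB4 at 95.8%, 32.5% and 52.8% against 36.8% and 9.09%. WNT pathway antagonists had a median difference of 13.0 points over 21 promoters (camera adjusted p = 0.0873, upward, and 0.0149 without LNCaP, both with the preset correlation, and 0.495 over all lines with an estimated correlation). SFRP2, a secreted WNT inhibitor, was at 95.5%, 32.1% and 84.2% against 11.6% and 18.6%, and SOX17 at 40.4%, 24.7% and 83.1% against 8.82% and 21.9%.

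Median differences of further lists were 3.95 points for epithelial junction and identity genes, 5.19 for mesenchymal and stromal genes and 2.76 for both leukocyte and imprinted genes, where the imprinted median was 0.312 with 200 bp to each side, 5.05 without LNCaP and 6.39 without RWPE-1. They were 2.47 for tumour suppressor and DNA repair genes, 1.40 for the DNA methylation machinery, 3.37 for zinc finger genes of chromosome 19 and 0.658 for cytosolic ribosomal protein genes. With a line left out these ran from 0.653 to 3.39, 0.281 to 3.75, 1.24 to 6.28 and 0.236 to 1.77 points in the same order. Camera's adjusted p lay between 0.0768 and 0.683 over the 12 lists, which include the protocadherins, the WNT antagonists and the glutathione genes. Camera's direction was downward relative to other promoters in 11 of these 12 lists although every median difference was above 0, and for mesenchymal genes it turned upward when centred on the ribosomal promoters. CDH1, the epithelial cadherin, was at 25.8% ± 15.3 (SD, n = 3) against 21.2% ± 11.4 (SD, n = 2), and its difference of 4.68 points became -2.28 without Du145 and -3.40 without PWR-1E. CDKN2A, the cell cycle inhibitor locus, was at 4.25% ± 6.10 (SD, n = 3) against 4.11% ± 3.11 (SD, n = 2). This promoter lies at the outer end of the gene (chromosome 9, 21994824 to 21996324). Starts inside the gene were not examined as promoters, so the levels hold for this end alone.

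Further members of these lists were named by size alone. FKBP5, an androgen-induced cochaperone, was at 26.1% ± 10.4 (SD, n = 3) against 6.46% ± 3.35 (SD, n = 2). Its difference of 19.7 points was 11.7 with unweighted means at the sites passing in all 5 libraries. FOLH1, the prostate-specific membrane antigen, was at 61.9% in Du145, 31.0% in LNCaP and 18.3% in PC-3 against 13.4% in PWR-1E and 24.1% in RWPE-1. The FOLH1 difference of 18.3 points became 5.90 without Du145. It was 13.9 with unweighted means at the sites passing in all 5 libraries, where LNCaP was at 13.5%. RAB25, an epithelial trafficking GTPase, was at 56.8% ± 19.3 (SD, n = 3) against 25.6% ± 10.8 (SD, n = 2). Its difference of 31.2 points was 21.0 with unweighted means at the sites passing in all 5 libraries. There PWR-1E was at 38.55% and LNCaP at 38.59%. TWIST1, a mesenchymal factor, was at 71.3% in Du145 and 7.54% to 25.2% in the other lines. The T cell gene CD3E was at 62.8% ± 27.7 (SD, n = 3) against 32.7% ± 18.3 (SD, n = 2). Its difference of 30.1 points became -7.97 with 200 bp to each side and ran from 17.2 to 46.0 with a line left out. The CD3E end (chromosome 11, 118315673 to 118317173, 25 sites) was inferred from CpG sites alone, so this region may not be its promoter. The lymphoid factor IKZF1 was at 65.4% ± 16.9 (SD, n = 3) against 38.4% ± 15.01 (SD, n = 2). Its difference of 27.0 points ran from 16.4 to 37.6 with a line left out. The imprinted gene ZDBF2 was at 19.3%, 42.1% and 74.0% in Du145, LNCaP and PC-3 against 0.809% and 6.24%, and NDN at 66.2% ± 25.3 (SD, n = 3) against 37.9% ± 25.2 (SD, n = 2), a difference of 28.3 points that ran from 10.4 to 46.1 with a line left out. DAPK1, a pro-apoptotic kinase, was at 60.04% ± 6.84 (SD, n = 3) against 38.9% ± 19.02 (SD, n = 2). Its difference became -6.77 points with 200 bp to each side and 7.73 without PWR-1E. With unweighted means at the sites passing in all 5 libraries DAPK1 was high in PC-3 alone, at 64.8%. Du145 and LNCaP were there at 19.8% and 25.05%, and PWR-1E and RWPE-1 at 20.05% and 25.6%. RASSF5 was at 37.7% ± 5.48 (SD, n = 3) against 21.2% ± 2.82 (SD, n = 2). TET2, a demethylating enzyme, was at 93.6% in LNCaP, 17.9% in Du145, 9.02% in PC-3, 9.82% in PWR-1E and 43.0% in RWPE-1. UHRF2 was at 38.5% ± 11.5 (SD, n = 3) against 22.9% ± 17.3 (SD, n = 2). Its difference of 15.6 points became -0.0228 with 200 bp and ran from 3.36 to 27.8 with a line left out. The zinc finger gene ZNF577 passed when adjusted over its list of 199 (adjusted p = 0.0395, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 96.7% ± 1.10 (SD, n = 3) against 28.4% ± 17.3 (SD, n = 2), and ZNF177 was at 80.8% ± 23.6 (SD, n = 3) against 29.7% ± 0.483 (SD, n = 2). In the ribosomal control list the largest differences were 14.4 points at RPL31, which became -0.189 with 200 bp, and 14.2 at RPL15, which became 2.17 with 200 bp and 3.74 with unweighted means at the sites passing in all 5 libraries.

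With promoters of 200 bp to each side of the 5′ end, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 14 of 12338 promoters, all higher in cancer, at adjusted p from 0.0407 to 0.0457. Among them were HOXA7, HOXB4, CCDC8, SPAG6, VWC2, GALR1, RASGRF2, COL7A1, SLC6A15, IGFBP7, LURAP1, ZNF804A and RGS7. In this shorter promoter HOXA7 was at 98.6%, 88.2% and 91.4% in Du145, LNCaP and PC-3 against 0.849% and 4.69%. IGFBP7, an insulin-like growth factor binding protein, was at 28.8%, 76.7% and 83.3% against 1.14% and 0.490%. COL7A1, the anchoring fibril collagen, was at 46.5%, 79.7% and 74.6% against 0.318% and 0%. Among promoters of the standard length chosen after their values were seen, 9 of the 10 largest separated differences upward were at SIM1, KRT5, TRIM54, VWC2, FUT9, GALR1, WNK3, EFCC1 and SPAG6, from 80.9 to 72.3 points. The 10 largest downward were at CLCN4, SPRR2G, CXCL5, PLEKHA4, LELP1, PCDHA5, S100PBP, FAM47A, ASB5 and DDAH1, from -64.8 to -35.9 points. As elsewhere, these ends were inferred from CpG sites alone. The regions given for TRIM54 (chromosome 2, 27306935 to 27308435) and PLEKHA4 (chromosome 19, 48836097 to 48837597) may therefore not be the promoters of these genes. DDAH1 was at 0% in Du145 and at 83.97% to 94.5% in the other lines, so its difference was -7.32 points without Du145, and with a line left out that of FAM47A ran from -54.8 to -19.2 and that of S100PBP from -57.5 to -23.3 points. SPRR2G and LELP1 belong to the epidermal differentiation complex on chromosome 1: SPRR2G was at 8.66% ± 12.7 (SD, n = 3) against 65.9% ± 13.5 (SD, n = 2) and LELP1 at 25.2% ± 29.96 (SD, n = 3) against 70.7% ± 12.9 (SD, n = 2). CXCL5, a neutrophil chemokine, was at 31.5% ± 20.5 (SD, n = 3) against 82.4% ± 8.99 (SD, n = 2).

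CpG-dense regions, which include many regions outside promoters, leaned the same way but held more regions lower in cancer. The largest separated differences, chosen after the values were seen, were at chromosome 6, 26171673 to 26172704, with 96.3% ± 2.41 (SD, n = 3) against 0.0844% ± 0.119 (SD, n = 2), at chromosome 1, 121117825 to 121118919, and at chromosome 19, 45402113 to 45403018, in PPP1R13L, with 96.1% ± 1.40 (SD, n = 3) against 1.56% ± 1.39 (SD, n = 2). The largest downward ones were at chromosome 5, 85638428 to 85638915, at chromosome 11, 1869537 to 1870096, in the leukocyte gene LSP1 (14.6% ± 12.4, SD, n = 3, against 88.5% ± 4.92, SD, n = 2), and at chromosome 2, 65640156 to 65640651. Of 51185 regions, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 2876 at an unadjusted p under 0.05, 2754 of them higher in cancer, and a smallest adjusted p of 0.0669. Limma called 1 higher, the region on chromosome 6 (adjusted p = 0.0292 with Benjamini-Hochberg adjustment), and the likelihood ratio test of edgeR 311 higher and 14 lower. All 3 cancer lines lay at least 20 points in the mean above both normal lines in 3596 regions and below them in 517. Without a minimum difference 19.7% were separated, against 20% by chance order. Without Du145 the quasi-likelihood test called 39 regions higher and 4 lower, and the regions separated downward became 2805. They became 1074, 1305 and 1167 without PC-3, PWR-1E or RWPE-1, and without LNCaP those separated upward became 5970.

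The second comparison asks whether the cancer lines have lost methylation over large stretches of the genome. LNCaP had the lowest genome-wide level, at 51.1%, and Du145 the highest, at 77.4%. PC-3 (68.3%) lay between the normal lines, PWR-1E at 64.5% and RWPE-1 at 70.7%. Sites between genes were at 41.4% in LNCaP and at 67.9% to 77.8% in the other lines. Promoter sites, by contrast, were at 18.0%, 17.03% and 16.8% in Du145, LNCaP and PC-3 and at 10.7% and 12.4% in PWR-1E and RWPE-1.

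The genome-wide level was 65.6% ± 13.4 (SD, n = 3) in the cancer lines and 67.6% ± 4.37 (SD, n = 2) in the normal lines, a difference of -2.04 points that is smaller than the spread between lines (two-sided exact permutation test, p = 0.9; the smallest possible p is 0.1). It was 5.22 points without LNCaP, 1.05 without RWPE-1, -7.95 without Du145 and 0.339 at the sites passing in all 5 libraries. In 2 further planned settings it was -0.292 points with a coverage minimum of 10 reads and -0.507 points weighted by reads. PC-3 lay 3.74 points above PWR-1E, and the mean of Du145 and LNCaP differed from RWPE-1 by -6.47 points. By annotation, cancer minus normal was 5.72 points in promoters (two-sided exact permutation test, p = 0.1, the smallest possible), 5.52 in CpG-dense regions (exact p = 0.4), 0.301 in their shores (exact p = 1), -2.94 in gene bodies (exact p = 1) and -7.41 between genes (exact p = 0.9). Without LNCaP the differences in CpG-dense regions, shores, gene bodies and between genes were 9.03, 6.85, 4.64 and 3.13 points, and without Du145 they were 3.29, -4.15, -7.95 and -15.1 points. Without PC-3 they were 4.25, -1.80, -5.52 and -10.3 points. At the sites passing in all 5 libraries the same 4 were 5.87, 1.71, -0.827 and -4.74 points.

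**Figure D4:**
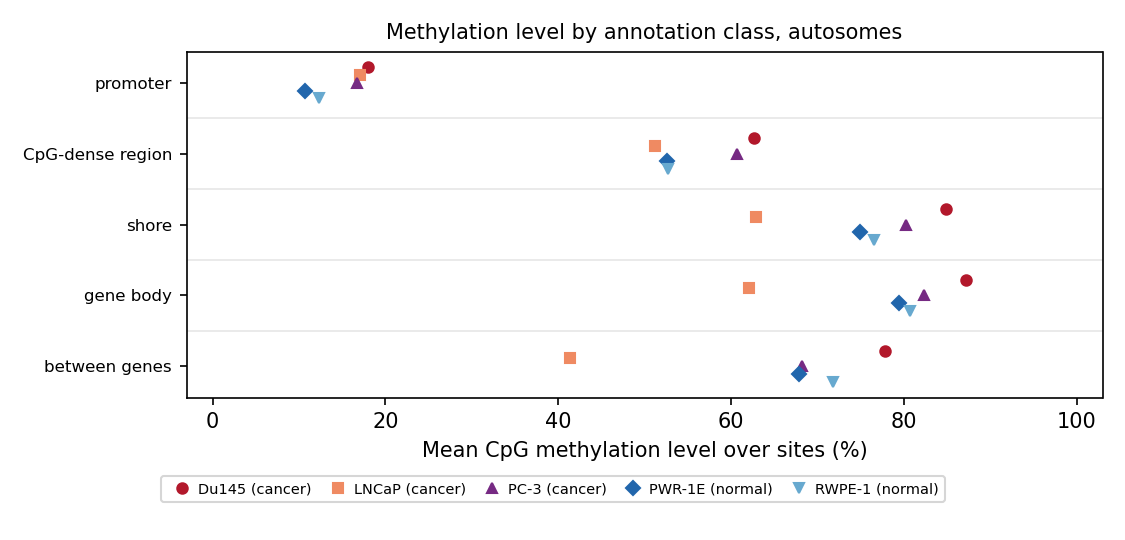
Mean methylation level in percent (x axis) over autosomal CpG sites of 5 annotation classes (y axis) in each line, with 1 point per library and no error bar. Promoters are at 16.8% to 18.0% in the cancer lines and at 10.7% and 12.4% in the normal lines, and between genes LNCaP is at 41.4% with the other lines at 67.9% to 77.8%.

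Partially methylated 10-kb windows, with a mean site level under 60%, made up 50.2% of 126498 windows in LNCaP, 15.4% in Du145, 27.6% in PC-3, 28.8% in PWR-1E and 22.2% in RWPE-1. The cancer lines had 31.1% ± 17.7 (SD, n = 3) and the normal lines 25.5% ± 4.72 (SD, n = 2), a difference of 5.57 points (two-sided exact permutation test, p = 0.9), which was -4.01 points without LNCaP, 13.4 without Du145 and 2.23 without RWPE-1. It was 2.43 points with a coverage minimum of 10 reads and 8.54 in windows with no CpG-dense region and no promoter. PC-3 minus PWR-1E was -1.25 points, and the mean of Du145 and LNCaP minus RWPE-1 was 10.7 points. In LNCaP 24884 windows were partially methylated in that line alone, against 388 in Du145, 1112 in PC-3, 1641 in PWR-1E and 374 in RWPE-1.

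Of the 100-kb windows, those without a protein-coding gene differed by -10.4 points between the group means and those with genes by -0.225 points. Without LNCaP the differences were -0.251 and 5.88 points, without RWPE-1 -6.51 and 5.28, without Du145 -18.3 and -6.50 and without PWR-1E -14.3 and -5.73 points, in settings added after seeing the data. In 8929 windows without such a gene the mean level was 33.8% in LNCaP, 69.8% in Du145, 58.7% in PC-3, 60.6% in PWR-1E and 68.4% in RWPE-1, and in 17838 windows with genes 54.2%, 78.9%, 66.01%, 61.1% and 72.1% in the same order. The windows with the largest separated differences, chosen after their values were seen, lay lower in cancer at chromosome 20, 55500001 to 55600000, with 20.4% ± 30.8 (SD, n = 3) against 88.1% ± 3.94 (SD, n = 2), and at chromosome 16, 82700001 to 82800000 and 82800001 to 82900000, in the cadherin gene CDH13. At the second of these CDH13 windows Du145 was at 50.5%, LNCaP at 3.69% and PC-3 at 9.82%, with PWR-1E at 87.8% and RWPE-1 at 89.3%. The largest upward differences were at chromosome 4, 133100001 to 133200000, which holds the protocadherin gene PCDH10 (69.9% ± 8.69, SD, n = 3, against 20.1% ± 14.6, SD, n = 2), at chromosome X, 114500001 to 114600000, in HTR2C, and at chromosome 22, 47700001 to 47800000. Of 26767 windows edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0, with 435 at an unadjusted p under 0.05, 102 higher and 333 lower in cancer, and a smallest adjusted p of 0.165; limma and the likelihood ratio test also called 0. All 3 cancer lines lay at least 20 points in the mean below both normal lines in 1027 windows, 697 of them without a protein-coding gene, and above them in 214. Without a minimum difference 8.15% were separated, against 20% by chance order. Without Du145 the quasi-likelihood test called 95 windows lower and 3 higher. The windows separated downward became 4151 without Du145, 651 without LNCaP, 2066 without PC-3 and 2391 without PWR-1E, and those upward 1130 without LNCaP, 611 without PC-3, 82 without PWR-1E and 2466 without RWPE-1.

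Each cancer line was then set beside both normal lines. LNCaP alone had high methylation at LGALS3, which encodes galectin-3 (96.8%, exact 95% interval 95.7 to 97.6, against 0.233% to 3.14% in the other lines), and at OVOL2, an epithelial transcription factor (71.9%, 68.3 to 75.4, against 0.482% to 9.26%). It alone had low methylation at the olfactory receptor promoters OR11L1 (5.66%) and OR7G3 (2.53%). Du145 alone had high methylation at CDH2, the mesenchymal N-cadherin (87.7%, exact 95% interval 86.4 to 89.0, against 0.562% to 9.95%), at the transcription factor genes ISL1 (84.4%) and IRX2 (69.0%), and at TIMP3, a metalloproteinase inhibitor (81.7%). PC-3 alone had high methylation at PCDHGC3 (97.0%) and ZNF587 (72.9%) and low methylation at the cancer-testis gene MAGEA3 (11.4%, exact 95% interval 3.20 to 26.7, over 35 reads, against 72.3% to 84.7%).

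Promoters at least 50 points above both normal lines numbered 358 in Du145, 269 in LNCaP and 391 in PC-3, and those at least 50 points below both 13, 65 and 8, out of 13065. In CpG-dense regions 1142, 874 and 1137 lay above and 171, 2521 and 181 below. Du145 and PC-3 shared 103 of the promoters above, LNCaP and PC-3 91, Du145 and LNCaP 50, and all 3 lines 23. Independent lists of these sizes would share 10.7, 8.05, 7.37 and 0.221. The comparisons share the same 2 normal lines, which by itself makes lists overlap. Simulated unchanged lines set against these gave 33.8 promoters per line, 1.21 shared by 2 lines and 0.03 by 3 lines over 100 draws. The simulated lists are far shorter than the real ones, so their shared counts cannot be set beside those of the real lines. How much of the sharing comes from the shared normal lines, up to all of the excess, stays open. The counts of the real lines carry no test, since each line has 1 library.

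Across promoters, PWR-1E and RWPE-1 were the most alike of the 10 pairs of lines (Pearson r = 0.907 across 13065 promoters, which are not independent replicates), and 48 promoters differed between them by 50 points or more. Du145 and LNCaP were the least alike (r = 0.708, 724 promoters). Among the cancer lines Du145 and PC-3 had the highest r, at 0.826, below the r of 0.839 between Du145 and RWPE-1, an order that turned with unweighted means at the sites passing in all 5 libraries (0.848 and 0.842). Across 100-kb windows PWR-1E and RWPE-1 again had the highest r (0.797) and LNCaP and PWR-1E the lowest (0.382), which at sites passing in all 5 libraries was 0.529, where LNCaP and RWPE-1 were lowest at 0.437.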

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

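The tests in this part were chosen after the results were seen, although the genome-wide level and its value at the sites passing in all 5 libraries were planned. Reads were nearly missing over long stretches in single cancer lines, a signal in the coverage that no comparison above uses. A stretch was at least 5 windows of 10 kb holding under 1% of the reads of the lowest other line. Du145 had 1, on chromosome 6 at SAMD5 (147810001 to 147950000), with 3 reads against 3958 or more in each other line. LNCaP had 1, and PC-3 had 9, of 1840 kb in all. The longest was on chromosome 10, overlapping RNLS and LIPJ (88010001 to 88640000, 10 reads against 20865 or more), followed by chromosome 17, overlapping STAT5B (42110001 to 42510000), where the neighbouring STAT3 gene had 49 reads against 11387 or more. Another overlapped CTNNA1, of which it held a part, on chromosome 5. The tables argue against the uneven coverage of the PC-3 library as the source of its 9 stretches, because PWR-1E, the other library of that kind, had 0, as had RWPE-1. Sequence where no library's reads can be placed is left out by the definition of a stretch, which needs reads in every other line. Loss of the sequence from the line, and reads that could not be placed there in that line alone, stay open as untested explanations. No biological explanation was tested.

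The genome-wide level moved in opposite directions in 2 cancer lines: Du145 lay 6.70 points above the higher normal line, and LNCaP minus the lower normal line was -13.5 points. This difference between the lines was not tested, since each has 1 library. For the low level of LNCaP, a different set of covered sites is argued against, since at the sites passing in all 5 libraries LNCaP still lay 9.63 points below the lowest other line. A uniform loss of methylated calls is argued against as well: in 10-kb windows at 85% or more in the other 4 lines the median of LNCaP was 84.7%, with a lower quartile of 75.5%, where scaling by the genome-wide ratio would give 70.1%. A difference of the LNCaP line itself, greatest where the other lines are also below full methylation, stays open as a hypothesis that rests on 1 library.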

How the results depend on the processing

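No paired analysis was possible because the replicate numbers only name the lines, and no cancer line is matched to a normal line. Chosen after seeing the data were the sites passing in all 5 libraries (planned only for the genome-wide level), unweighted site means, coverage evenness as a term, a density of 35 sites and ribosomal centring. So were levels standardised by CpG density, means over 10-kb windows, and leaving out lines for 100-kb windows by gene content; the other alternatives were planned. The CpG island settings and repeat-masked sequence were not run, for lack of a genome sequence. The cause of each change below was not tested, apart from fewer lines when one is left out. Thinning the reads to the shallowest library moved the separated promoters little, to 882 upward and 35 downward. The quasi-likelihood test of edgeR called 0 with and without thinning, which says nothing about depth. The promoter count upward also stayed within 1.5 times of 881 with 10 reads, every deposited site, no upper limit, autosomes alone, at least 10 sites, other promoter lengths, common sites and unweighted means.

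Calls appeared under some settings. By the likelihood ratio test of edgeR there were 91 promoters higher and 1 lower and 311 CpG-dense regions higher and 14 lower, and 0 windows. A promoter of 200 bp to each side gave 14 higher, and for CpG-dense regions limma gave 1 higher and a minimum of 10 reads 1 higher. Leaving out 1 line gave from 0 to 39 CpG-dense regions higher and 0 to 4 lower, and 0 to 3 windows higher and 0 to 95 lower, in each case with calls only without Du145, and 0 promoters either way. Coverage evenness as a term gave 0 calls for all 3 kinds of region. The quasi-likelihood test called 0 without that term too, so this cannot show whether coverage matters.

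The separated counts depended on the minimum difference: with none they were 2722 promoters higher and 192 lower, 8556 CpG-dense regions higher and 1509 lower, and 880 windows higher; with 40 points they were 312 and 7, 1227 and 116, and 16 and 269. Regions lower in cancer were 24 promoters with 2000 bp to each side, 328 CpG-dense regions and 657 windows with 10 reads, and 107 CpG-dense regions with at least 35 sites. Windows higher were 339 at common sites, and with windows of 50 kb 474 were higher and 2061 lower. Leaving out each line in turn, where chance order separates 33.3% or 50% of regions and not 20%, gave 1059 to 1361 promoters higher and 57 to 143 lower, 4176 to 5970 CpG-dense regions higher and 460 to 2805 lower, and 82 to 2466 windows higher and 651 to 4151 lower.

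Of the list tests 8 passed, 7 at common sites, where the cancer-testis list did not, 8 with ribosomal centring, 6 to 9 when a line was left out, and 0 by camera with an estimated correlation. The difference in genome-wide level was 0.339 points at common sites and -7.95 to 5.22 with a line left out, and that in the share of partial windows 2.43 with 10 reads, 8.54 in windows with no CpG-dense region and no promoter, and -4.01 to 13.4 with a line left out. By gene content, leaving out a line gave -18.3 to -0.251 in 100-kb windows without a protein-coding gene and -6.50 to 5.88 in windows with genes, where it was 5.88 without LNCaP and 5.28 without RWPE-1. By annotation, leaving out a line gave 3.29 to 9.03 in CpG-dense regions, -4.15 to 6.85 in shores, -7.95 to 4.64 in gene bodies and -15.1 to 3.13 between genes, while the promoter difference stayed between 4.89 and 6.55. At 30 points the promoters above and below both normal lines were 841 and 49 in Du145, 716 and 194 in LNCaP and 857 and 37 in PC-3. With 10 reads LNCaP had 39 below, and with unweighted means Du145 had 20 below. The r of PWR-1E and RWPE-1 was 0.938 across promoters, 0.941 across CpG-dense regions and 0.856 across windows with unweighted means.

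Of 809 differences at 76 named promoters under the alternatives, 793 kept their direction. Many of these promoters were named for a large difference in the same data. Where all 3 cancer lines lay on the same side of both normal lines, leaving out a line cannot turn the direction. The count is therefore no measure of how far the directions would hold in other data. With 200 bp to each side CD3E was -7.97, DAPK1 -6.77, RPL31 -0.189 and UHRF2 -0.0228. With a line left out the ranges that crossed 0 were CDH1 -3.40 to 12.9, TIMP3 -3.23 to 35.3, CDKN2A -3.38 to 2.34, CGAS -6.31 to 15.8, OR7G3 -30.6 to 8.56, OVOL2 -3.65 to 32.0, TET2 -13.0 to 30.3, TP63 -5.88 to 0.283 and MAGEA3 -30.6 to 6.01. Of 209 list medians 191 lay within the SD between the medians of the 3 cancer lines from the value over all lines, which in some lists is wide: with a line left out the protocadherin median ran from 3.83 to 36.1, that of the DNA methylation machinery from 0.281 to 3.75, that of epithelial junction genes from 0.664 to 5.55 and that of WNT antagonists from 8.05 to 13.7. The imprinted median was 0.312 with 200 bp, 5.05 without LNCaP and 6.39 without RWPE-1. The basal epithelial median was 14.1 at common sites, 9.93 unweighted and 14.4 to 32.4 with a line left out. The cancer-testis median was 1.18 with 10 reads, 0.364 at common sites, 0.329 unweighted and -5.01 to 4.72 with a line left out. The antigen presentation median was -0.0221 with 200 bp, -0.244 at common sites, -0.261 unweighted and -0.387 to 1.64 with a line left out, and the olfactory median -18.7 to 5.32.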

Other observations

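The tests in this part were chosen after the results were seen, apart from edgeR's tests of the real split. Separated counts were added after seeing the data. Partially methylated windows overlapped between the lines. Of the 126498 windows of 10 kb, 14127 were under 60% in all 5 lines, against 172 if the lines were independent. Of the smaller set of a pair of lines, 79.4% (PC-3 and PWR-1E) to 90.8% (Du145 and LNCaP) also lay in the larger set. These counts include windows with a CpG-dense region or promoter, which can be low in every line. In the 84897 windows with neither, 8.68% were under 60% in Du145 against 15.4% of all windows, and 46.2% against 50.2% in LNCaP. The overlap was not computed for these windows alone, so part of it may come from CpG-rich sequence. LNCaP was lowest of the 5 lines on every chromosome from 1 to 22, from 44.8% on chromosome 4 to 58.4% on chromosome 17. Promoters with few and with many CpG sites leaned the same way. In the third with 20 to 76 sites 321 promoters were separated upward by at least 20 points and 30 downward, in the third with 77 to 106 sites 277 and 6, and in the third with 107 to 277 sites 283 and 1.

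Some prostate genes could not be assigned a 5′ end, and both ends are given where they were measured, without a test. HOXB13, a homeobox factor of the prostate lineage, was at 86.6% in Du145 around the end with the higher coordinate (chromosome 17, 48728250 to 48729750) and at 0.589% in LNCaP, 5.69% in PC-3, 7.79% in PWR-1E and 12.6% in RWPE-1. Around its other end the levels were 48.7%, 5.56%, 2.28%, 20.5% and 29.1% in the same order. KLK3, which encodes prostate-specific antigen, was at 79.3% in Du145, 18.4% in LNCaP, 17.3% in PC-3, 34.6% in PWR-1E and 57.8% in RWPE-1 around the end with the lower coordinate (chromosome 19, 50853915 to 50855415), over 150 to 560 reads per line. Around its other end the levels were 62.3%, 13.7%, 25.1%, 34.2% and 32.9%. CDKN1A around its lower end was at 94.8%, 87.0%, 81.0%, 69.0% and 67.9% in the order Du145, LNCaP, PC-3, PWR-1E and RWPE-1.

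More promoters were higher than lower in the cancer lines, with 881 separated upward and 37 downward. The uneven coverage of PC-3 and PWR-1E is argued against as the whole source: between lines with the same kind of coverage, among promoters at least 20 points apart, 88.5% were higher in PC-3 than in PWR-1E, 89.99% in Du145 and 73.7% in LNCaP than in RWPE-1. Incomplete conversion of the cancer libraries is argued against too, since the median level of the ribosomal protein promoters at common sites differed by at most 1.16 points between any cancer and any normal line. The 10 splits of the 5 libraries into 3 and 2 are too few for a share under 0.05. The real split gave 918 separated promoters, and the highest other split gave 1004 (Du145 and PC-3 against the rest). Counting the real split itself, 2 of the 10 gave 918 or more. The split by coverage, PC-3 and PWR-1E against the rest, gave 583 separated promoters, falling to 168 with unweighted levels at common sites where the real split gave 829, but it gave the most promoters of all splits at an unadjusted p under 0.05 by edgeR's quasi-likelihood test (2112, then 892 for Du145 and PC-3 and 797 for the real split). The likelihood ratio test called 161 for the split by coverage, 157 for Du145 and PC-3, 96 for LNCaP and PC-3 and 92 for the real split, so an excess of likelihood ratio calls is not particular to coverage. At an unadjusted p under 0.05 the split by coverage stood far above the others.

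The technical split was visible in promoters with low levels. The median of the ribosomal protein promoters, summed over reads, was 6.01% in Du145, 5.05% in LNCaP and 5.10% in RWPE-1 but 2.06% in PC-3 and 1.04% in PWR-1E. As unweighted site means at sites passing in all 5 libraries it was 0.964%, 0.688%, 0.759%, 1.81% and 0.651% in the same order. Whether cancer status, metastatic site or the basal or luminal origin of a line accounts for the promoter differences was not tested, since each line has 1 library and the groups differ in all of these.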
